A study of Mus musculus with 38 samples.

How the data were processed

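Bulk RNA sequencing of mouse retina was analysed for 15 libraries in 5 groups of 3. The groups were wild type at 1, 6, 12 and 18 months of age and mice heterozygous for Kdm3b at 12 months. The labels list 38 samples in all, and the 4 single-cell and 19 chromatin immunoprecipitation samples were not analysed here. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from polyadenylated RNA with a kit that marks strand, although the protocol also describes an oligo-dT-primed first strand. The submitters' processing notes name CASAVA, Trim Galore 0.6.6, STAR 2.7.1a, RSEM 1.3.3, DESeq2 1.32.0 and edgeR 3.36.0, without roles or order. The annotation release and the strand setting were not given in the sources used here.

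The deposited table holds expected counts, estimated by the authors for 142699 Ensembl transcripts in each library, and 99045 of them had a count in at least 1 library. Expected counts share reads between transcripts that overlap in sequence, so a value of 0 can mean that reads were given to another transcript. Each value was rounded to a whole number here before testing. The table has no column besides these 15 libraries. Transcript identifiers were compared with the gene names in the reference tables, and 0 matched. The files do not pair the identifiers with gene names, so counts could not be summed per gene, the level of Kdm3b could not be read in any library, and the gene lists and cell type lists fixed before the data were examined could not be run. The same tests were run on transcripts, as the design had set out for that case.

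The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling, robust dispersion and a filter on low counts over the 5 groups, which kept 53952 transcripts. All 15 libraries entered 1 fit with a mean per group and 10 residual degrees of freedom. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic, which is an approximation. Levels are CPM, counts relative to the scaled library total, computed here after TMM scaling, given as mean and SD over 3 libraries. A fold against a group with 0 reads in all 3 libraries was computed against a floor of 3 counts per library and is a lower bound. The fitted log2 fold change against such a group depends on the small count that edgeR adds and is no bound. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

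A transcript was counted as separated when all 3 libraries of 1 group lay above all 3 of the other, among the 14367 transcripts with a mean of at least 10 CPM; chance gives 10%. Transcripts higher or lower at 18 months than at 1 month were tested as sets in the heterozygous comparison with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2). Fewer than 10 transcripts passed in each direction, so each set held the 200 with the lowest p, as fixed beforehand. The named transcripts were chosen by the rule fixed beforehand: those past the threshold with separated groups and, where none passed, the lowest unadjusted p values among 5, limited to 2 that were higher and 2 that were lower per comparison because no names could be given.

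The labels do not say whether replicates are separate animals, so p-values measure only the spread between these samples. No pair of libraries agreed within counting noise. The closest, replicates 2 and 3 of wild type at 12 months, differed by 9.14 times the counting variance, and the next pair by 17.1 times. Reads are not independent molecules, so this check cannot exclude libraries made from the same sample. The test was tried on simulated counts with known changes. At the spread estimated from these libraries it recovered 0% of 2-fold and 12% of 16-fold changes for the heterozygous comparison, and 0% and 18% for 18 months against 1 month. That spread was a dispersion estimated for each transcript, and the common value over all transcripts was 1.47. With 0.05 for every transcript instead, the test recovered 22% and 94%, and 26% and 94%. A count of 0 calls therefore does not show that expression was equal.

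For the comparisons and the age trend, 21 alternative settings were run besides leaving out each of the 15 libraries in turn. Of these, 9 were fixed before the data were examined and 12 were added afterwards. The fixed ones included DESeq2 (1.42.0), other scaling and filters, pairwise fits and a replicate block. The added ones were abundance minimums, transcripts with whole counts only (within 0.004), limma voom with library weights, libraries of low complexity left out, splits by depth, and forms of an age trend. The age trend, the separated counts and the tests of library complexity were chosen after the data were seen. Low complexity means that over 15% of the transcripts with a mean count of at least 20 had 0 reads, a limit set after those shares were seen.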

Results

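Transcript levels were measured in whole mouse retina from wild type mice at 4 ages and from mice heterozygous for Kdm3b, a gene whose product removes methyl groups from lysine 9 of histone H3. Total counts ranged from 9568801 to 32851304 per library. The wild type libraries at 1, 6 and 18 months held 17169253 to 19826859. At 12 months, replicate 1 was deeper than the others in both genotypes: 16009261 against 9732001 and 9604683 in wild type, and 32851304 against 10289551 and 9568801 in the heterozygous group.

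The libraries differed in how many transcripts they detected, and depth did not set the order. Replicates 2 and 3 at 1 month, replicate 2 at 6 months and replicate 1 at 18 months detected 37489, 40426, 34477 and 42474 transcripts. The other 11 libraries detected 51843 to 68013. In those 4 libraries, 18.8% to 28.5% of the transcripts with a mean count of at least 20 had 0 reads, and the highest share in any other library was 14.2%, in replicate 3 of the heterozygous group. The median Spearman correlation between libraries, across transcripts, was 0.706 within groups (15 pairs) and 0.714 between groups (90 pairs).

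**Figure D1:**
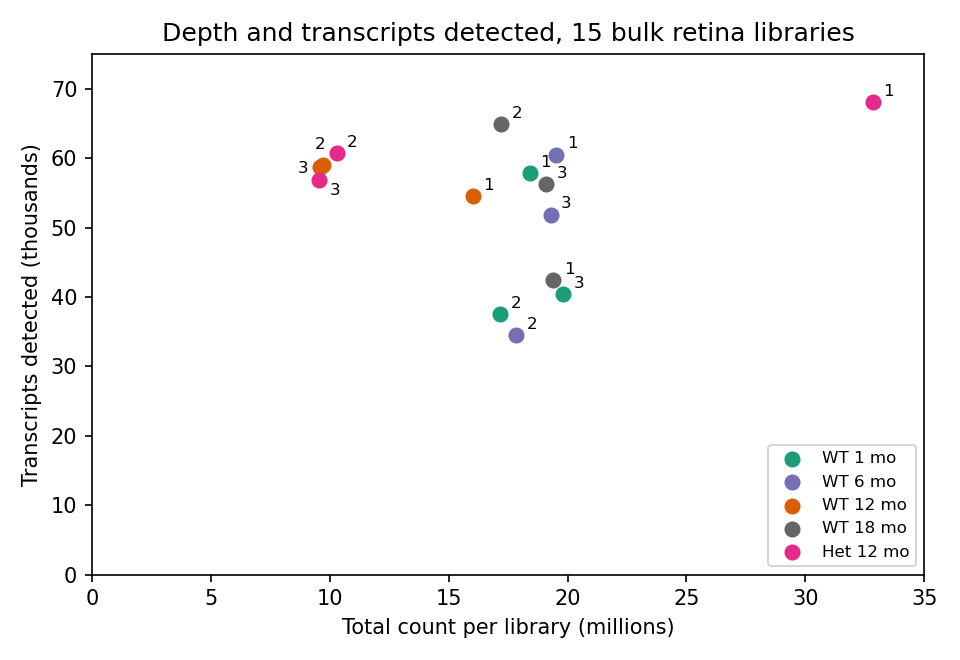
Each point is 1 bulk retina library, with its total count on the x axis and the number of transcripts detected on the y axis; colours give the group and the digit gives the replicate. The 4 lowest libraries, at 34477 to 42474 transcripts, have 17169253 to 19826859 counts, more than 5 libraries that detected more.

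The first comparison asked which transcripts differ in the retina of heterozygous mice at 12 months of age. ENSMUST00000179489 was at 10.1 ± 2.73 CPM (SD, n = 3) in heterozygous retina and had 0 reads in the 3 wild type libraries of that age, a level at least 36.1-fold higher. It was also at 15.1 to 17.9 CPM in wild type retina at 6 months, 9.39 to 15.8 CPM at 18 months, and 1.11, 16.4 and 15.1 CPM at 1 month, against 7.76 to 13.1 CPM in heterozygous retina. Wild type at 12 months was the only group of the 5 with 0 reads in all 3 libraries. These 0 values may also mean that reads were given to another transcript, as described under other observations. ENSMUST00000229930 was at 5.25 ± 6.38 CPM against 0 reads, at least 18.7-fold higher, with single heterozygous libraries at 12.6, 2.12 and 1.03 CPM, and at least 5.63-fold higher without replicate 1. It was present in all wild type libraries of the other ages, at 3.59 to 35.6 CPM. ENSMUST00000022587 was at 122 ± 16.5 CPM against 191 ± 21.4 CPM, a log2 fold change of -0.65 with a standard error of 0.158. None of these passed edgeR's quasi-likelihood test, with adjusted p of 0.415 for the first and 1 for the others. All 3 passed DESeq2 (adjusted p 7.07e-08, 3.46e-05 and 0.000872), and with limma voom the adjusted p values were 0.00598, 0.0602 and 0.0298.

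Of 53952 transcripts, 0 passed edgeR's test in this comparison and 723 (1.34%) had an unadjusted p under 0.05. DESeq2 called 327 and limma voom with library weights called 87. The voom weights were 0.958, 4.89 and 0.403 for the heterozygous replicates and 0.999, 3.96 and 5.17 for wild type at 12 months. Its results therefore rest mostly on replicate 2 of the first group and replicates 2 and 3 of the second. Of the DESeq2 calls, 242 were higher and 85 lower in heterozygous retina, and 314 of the 327 (96%) had 0 reads in at least 2 of the 3 libraries of a group. The groups were separated for 9.97% of the abundant transcripts, where chance gives 10%, with 387 higher and 1045 lower; with median-ratio scaling these were 536 and 788. With replicates 2 and 3 alone, which share a similar depth, 0 transcripts passed edgeR's test, and 0 passed with depth batch as a term. Without replicate 1 of the heterozygous group 4 passed, and without its replicate 3, 1 passed, all lower in heterozygous retina. The 4 calls rest on replicates 2 and 3 alone, which differed from replicate 1 in single transcripts, as given next. The labels do not give the sex of the animals, so sex and genotype cannot be told apart in this comparison.

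Replicates 2 and 3 of the heterozygous group stood apart from replicate 1 in single transcripts. ENSMUST00000127786, chosen after its values were seen, was at 2990 and 1050 CPM in those libraries, at 0.365 CPM in replicate 1 and at most 2.2 CPM in the 12 wild type libraries.

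The next comparison asked which transcripts differ between the oldest and youngest wild type retinas. ENSMUST00000152103 fell from 90 ± 38.5 CPM (SD, n = 3) at 1 month to 0 reads in all 3 libraries at 18 months, at least 566-fold lower, with an adjusted p of 0.0123 in edgeR's quasi-likelihood test. It was present in all 6 libraries at 12 months, at 49.7, 95.7 and 107 CPM in wild type and 43.7, 40.3 and 172 CPM in heterozygous retina. It was the only transcript of 53952 to pass. Its 0 reads may also mean that reads were given to another transcript. An unadjusted p under 0.05 was held by 3189 (5.91%), where chance alone gives a share of 0.05. DESeq2 called 910 transcripts, of which 76.7% had 0 reads in at least 2 libraries of a group, and limma voom called 4.

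The call of ENSMUST00000152103 ended when only the 6 libraries compared were fitted (edgeR adjusted p 0.839), also with a minimum of 10 CPM (adjusted p 0.349), and with limma voom (adjusted p 0.118). It also ended when the 4 libraries with few transcripts were left out (edgeR adjusted p 0.224), and when replicate 3 of the heterozygous group was left out as well (adjusted p 0.0599). These left 1 library at 1 month, assumed to vary like the other groups, at 133 CPM against 0 reads, at least 800-fold. The call held in 12 of 18 alternatives, over which the adjusted p ran from 1.65e-17, with DESeq2, to 0.839. Without replicate 1 at 1 month, which left the 2 libraries of that age with few transcripts, 227 transcripts passed, 221 of them higher at 18 months. Without replicate 1 at 18 months 5 passed. Groups were separated for 16.1% of the abundant transcripts, 992 higher and 1325 lower at 18 months.

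ENSMUST00000028838 had its lowest values at 1 month. It was at 13.1 ± 1.94 CPM at 1 month, 46.3 ± 15.3 CPM at 6 months and 49.4 ± 8.95 CPM at 12 months (SD, n = 3 each). The log2 fold changes over 1 month were 1.82 with a standard error of 0.318 and 1.91 with a standard error of 0.319. The groups were separated in both comparisons, but edgeR's adjusted p values were 1 and 0.623. It passed edgeR at 6 months without replicate 1 of that age (adjusted p 0.0388) and DESeq2 in both comparisons (adjusted p 0.000434 and 0.000605), and the highest adjusted p over the alternatives was 1 for each. At 18 months it was at 50, 71.9 and 72.6 CPM, with an edgeR adjusted p of 0.214 against 1 month. ENSMUST00000221317 had 0 reads in the 3 libraries at 1 month. It was at 14.3 ± 12.8 CPM at 6 months, at least 90.6-fold higher, or at least 43.6-fold without replicate 2, which has few transcripts and held 29 CPM. At 12 months it was at 8.75 ± 6.1 CPM (SD, n = 3 each), at least 55.6-fold higher, or at least 33.3-fold without replicate 1, with edgeR adjusted p of 1 and 0.623. Without replicate 1 at 1 month it passed edgeR in both (adjusted p 0.0434 and 0.0456), as it did with DESeq2 (adjusted p 6.99e-10 and 2.23e-08), and the highest over the alternatives was 1 for each. It also had 0 reads in the 3 libraries at 18 months.

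**Figure D2:**
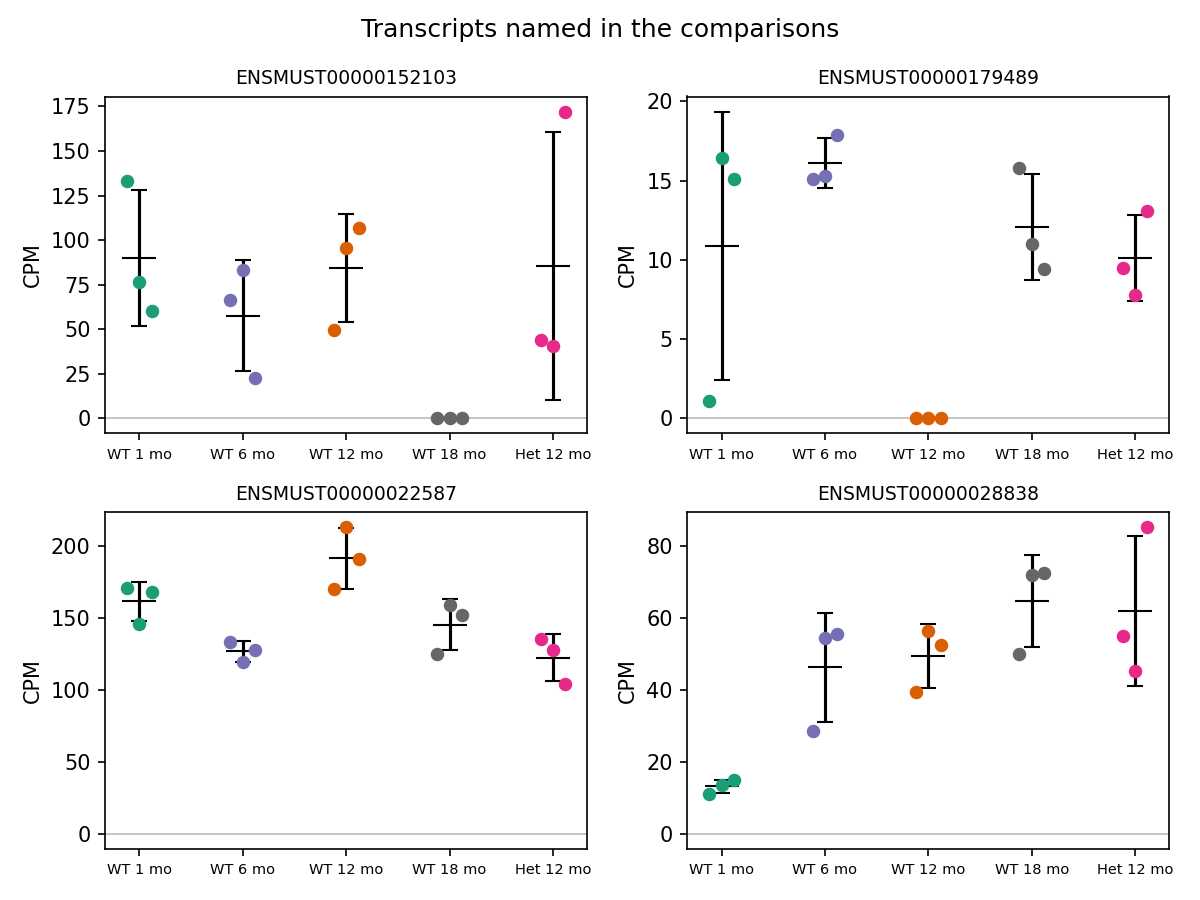
CPM of 4 named transcripts in each of the 5 groups, on linear axes; points are single libraries, and the bar and whiskers give the mean and SD of 3 libraries. ENSMUST00000152103 is at 0 in all 3 libraries at 18 months, and ENSMUST00000179489 in all 3 wild type libraries at 12 months.

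For 6 months against 1 month, 0 transcripts passed edgeR's test and 2443 (4.53%) had an unadjusted p under 0.05. DESeq2 called 630 and limma voom 0. Without replicate 1 at 1 month 169 passed, 168 of them higher at 6 months, and without replicate 1 at 6 months 25 passed, of which 1 was higher. Groups were separated for 8.2% of the abundant transcripts.

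For 12 months against 1 month, 0 transcripts passed edgeR's test and 3167 (5.87%) had an unadjusted p under 0.05. DESeq2 called 921 and limma voom 20. ENSMUST00000179489 had 0 reads at 12 months against 10.9 ± 8.48 CPM at 1 month (SD, n = 3), at least 38.8-fold lower, and ENSMUST00000229930 had 0 reads against 18.6 ± 12.4 CPM, at least 66.2-fold lower, with edgeR adjusted p of 0.384 and 0.623. Both passed edgeR without replicate 1 at 1 month (adjusted p 0.00025 and 0.0171), limma voom (adjusted p 0.0165 for each) and DESeq2 (adjusted p 7.75e-09 and 8.7e-09), and the highest over the alternatives was 1 for each. Replicates 2 and 3 at 1 month, which have few transcripts, carried these levels: replicate 1 alone held 1.11 and 6.29 CPM, giving at least 3.97-fold and 22.4-fold lower. Without replicate 2 the second was at least 43.8-fold lower. Without replicate 1 at 1 month 223 transcripts passed, 216 of them higher at 12 months, and without replicate 2 at 12 months 1 passed. Groups were separated for 23% of the abundant transcripts, 2258 higher and 1046 lower at 12 months, or 1779 and 1597 with median-ratio scaling.

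For 12 months against 6 months, 0 transcripts passed edgeR's test and 2406 (4.46%) had an unadjusted p under 0.05. DESeq2 called 667 and limma voom 63. ENSMUST00000190894 was at 6.1 ± 0.836 CPM (SD, n = 3) and ENSMUST00000166103 at 4.53 ± 4.36 CPM at 12 months, both with 0 reads in the 3 libraries at 6 months, and edgeR's adjusted p was 1 for each. The second was at 1.74, 2.29 and 9.56 CPM in single libraries, at least 28.3-fold higher, or at least 12.6-fold without replicate 3. It also had 0 reads in the 3 libraries at 1 month, where ENSMUST00000190894 was at 4.28, 1.48 and 1.27 CPM. ENSMUST00000179489 was at 16.1 ± 1.52 CPM at 6 months and ENSMUST00000229930 at 24.7 ± 12.3 CPM, with edgeR adjusted p of 0.258 and 0.64. The first passed edgeR without replicate 1 at 6 months (adjusted p 0.0322) and with no filter (adjusted p 0.0374). Both passed limma voom (adjusted p 0.005 and 0.011) and DESeq2 (adjusted p 9.94e-10 and 2.04e-09), ENSMUST00000190894 passed DESeq2 (adjusted p 7.84e-07), and the highest over the alternatives was 1 for each. Without replicate 1 at 6 months 30 transcripts passed, 29 of them higher at 12 months, and without replicate 2 at 12 months 1 passed. Groups were separated for 22.6%, 2256 higher and 990 lower, or 1726 and 1411 with median-ratio scaling.

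For 18 months against 12 months, ENSMUST00000152103 fell from 84.2 ± 30.4 CPM to 0 reads (SD, n = 3), at least 529-fold lower, with an edgeR adjusted p of 0.013. DESeq2 called 472 transcripts and limma voom 1025. The voom library weights were 0.239, 2.84 and 1.92 at 18 months and 0.999, 3.96 and 5.17 at 12 months. Replicate 1 therefore counted least on either side. ENSMUST00000152103 was the only transcript to pass edgeR's test, and 1602 (2.97%) had an unadjusted p under 0.05. The call ended on the 6 libraries alone (edgeR adjusted p 0.418), on these with a minimum of 10 CPM (adjusted p 0.231), without the 4 libraries with few transcripts (adjusted p 0.374), and without replicate 3 of the heterozygous group as well (adjusted p 0.165). The call also ended without replicate 1 at 18 months (edgeR adjusted p 0.0835) and without replicate 3 (0.0543). It held in 11 of 18 alternatives, over which the adjusted p ran from 3.66e-17 with DESeq2 to 0.418. Groups were separated for 25.1%, 913 higher and 2690 lower at 18 months, or 1378 and 1892 with median-ratio scaling. In the 3 age comparisons with wild type at 12 months above, TMM scaling put the median log2 ratio of abundant transcripts at 0.17, 0.14 and -0.12. Median-ratio scaling put it at 0.02, 0.02 and -0.03. For heterozygous against wild type retina it was -0.06 with TMM and 0.01 with median-ratio scaling, so its sign depended on the scaling. All 3 wild type libraries at 12 months are shallower than every library of the other ages. Replicate 1 is the closest, at 16009261 counts against at least 17169253, and replicates 2 and 3 are far below. Depth and this age therefore cannot be told apart.

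The last comparison asked whether the transcripts with the lowest p between 18 months and 1 month move in the heterozygous retina, with no library shared between the contrasts. Of the 200 on the higher side 0 had passed the age comparison, and of the 200 on the lower side 1 had, so the sets were not shown to differ with age. Of the 200 higher at 18 months, 118 were higher in heterozygous retina, with a median log2 fold change of 0.11 over the 199 with reads in both groups. The median over all transcripts tested was 0.025. Between 18 months and 1 month this set had a median log2 fold change of 6.81, at a median level of 1.83 CPM. At 1 month 2 libraries had few transcripts, so for this set age and library complexity cannot be told apart. The set did not pass camera (limma adjusted p 0.233, or adjusted p = 0.807 with an estimated correlation). Of the 200 lower at 18 months, 98 were higher in heterozygous retina, with a median of -0.01 over 178, and camera's adjusted p was 0.576, or adjusted p = 0.84 with an estimated correlation. With fry, adjusted p was 0.756 for each set.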

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

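The alternatives with limma voom, abundance minimums, whole-count transcripts, libraries left out for low complexity, depth and the forms of the age trend were chosen after the data were seen. Over the alternatives, 75 of 117 counts of calls stayed within 1.5 times the value reported and 42 moved. Of 248 values for the named transcripts, 210 kept direction and side of the threshold, 25 passed it newly, 13 lost it and 0 turned direction. Unless given below, the cause was not tested.

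The counts are given in the order heterozygous against wild type, then 6, 12 and 18 months against 1 month, 12 against 6 months and 18 against 12 months. DESeq2 called 327, 630, 921, 910, 667 and 472, and most of these transcripts had 0 reads in 2 or 3 libraries of a group (76.7% to 96%). limma voom called 87, 0, 20, 4, 63 and 1025, with library weights that ran from 0.179 to 5.17. Whole-count transcripts alone gave 0, 2, 6, 9, 0 and 0. Without the 4 libraries of low complexity the counts were 0, 0, 1, 3, 0 and 1, and without replicate 3 of the heterozygous group as well they were 1, 9, 10, 6, 0 and 1. Both settings leave 1 library at 1 month, assumed to vary like the other groups. In both, the 1 call for 18 against 12 months was higher at 18 months and was not ENSMUST00000152103, whose edgeR adjusted p there was 0.374 and 0.165. With no filter, 1 transcript passed for 12 against 6 months and 2 for 18 against 12 months. Fitting only the 6 libraries compared left 0 in each comparison, also among transcripts with a mean of at least 10 CPM. With replicate 1 as the only heterozygous library, assumed to vary like the other groups, 2 passed. Leaving out 1 library gave 0 to 4, 0 to 169, 0 to 223, 1 to 227, 0 to 30 and 0 to 1. Median-ratio scaling and minimums of 1, 10 and 50 CPM left the counts as reported.

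The replicate block left 0 calls in each of the 6 comparisons, including 18 months against 1 month and against 12 months, where ENSMUST00000152103 had edgeR adjusted p of 0.0876 and 0.187. The numbers were not shown to pair the samples throughout. Of 30 same-numbered pairs, 4 correlated above 0.1 (range -0.24 to 0.378), and 7 of 15 libraries correlated best with their own number. The highest were replicate 1 at 1 and 6 months (0.378) and replicate 1 of both genotypes at 12 months (0.366). A structure shared by some replicates is therefore not excluded.

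Neither set of transcripts ranked by age passed in the alternatives run for the set tests: the estimated correlation, fry, the replicate block, the sets from 18 against 6 months, each library at 12 months left out, and the low-complexity libraries left out with or without replicate 3 of the heterozygous group. The set lower at 18 months turned direction when the sets came from 18 against 6 months (limma adjusted p 0.553) and without replicate 2 of the heterozygous group (0.448), and its adjusted p over libraries left out ran from 0.0533 to 0.786. The age trend described under other observations gave 0 calls with linear age, 2 for any difference among ages, 2 without the low-complexity libraries and 1 to 7 with 1 library left out.

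Sums per gene, the level of Kdm3b and the fixed gene and cell type lists were planned but not run, because the files do not pair transcripts with genes. The share of separated transcripts moved with the abundance minimum, from 1 to 50 CPM: 8.09% to 11.7%, 7.36% to 8.79%, 17.7% to 28.6%, 13.8% to 19.4%, 17.3% to 26% and 18.2% to 32.7%, in the order above. Depth limits what low transcripts can show: 3 reads are a larger share of 9568801 counts than of 32851304.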

Other observations

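All tests in this part were chosen after the results they measure were seen. A trend of transcript level with log2 age over the 12 wild type libraries called 4 transcripts in edgeR's quasi-likelihood test. ENSMUST00000097425 was at 22.9 ± 4.58, 55.2 ± 6.06, 68.8 ± 4.46 and 88.9 ± 2.2 CPM at 1, 6, 12 and 18 months (SD, n = 3 each, edgeR adjusted p 0.00137), and ENSMUST00000135775 at 10.2, 30.7, 45.8 and 51.4 CPM (edgeR adjusted p 0.00825). ENSMUST00000062356 went the other way, at 40.3, 17, 15.2 and 10.2 CPM (edgeR adjusted p 0.0143). Linear age was tried first and called 0 of 51299 transcripts (3064 at an unadjusted p under 0.05). Log2 age was tried next because of that, and a test of any difference among ages then called 2. Judged by log2 age alone, 1 of 30 age assignments of the libraries, the real one, gave as many calls, and the highest other gave 1. That count ignores that the form was picked by its calls. Scored by the best of the 3 forms, 3 of 30 assignments gave at least 4, and the highest other gave 22, so chance is not excluded. Without the 4 libraries of low complexity 2 transcripts passed, and 0 of them were among the 4. Leaving out replicate 2 or 3 at 1 month, or replicate 2 at 18 months, left 1 call each. Leaving out replicate 3 at 12 or 18 months left 2 calls each, and leaving out replicate 2 at 6 months gave 7.

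For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Heterozygous against wild type gave 0 calls and the highest other split 2. The real and highest other counts were 0 and 1265 for 6 against 1 month, 0 and 0 for 12 against 1 month, 1 and 61 for 18 against 1 month, 0 and 1 for 12 against 6 months, and 1 and 1 for 18 against 12 months. At least as many calls as the real split came from 10, 10, 10, 6, 10 and 3 of the 10 splits. Where the real count was 0 this is 10 by construction and tells nothing. Counts at an unadjusted p under 0.05 also varied between splits. In the same order, the real and highest other were 723 and 2063, 2443 and 8881, and 3167 and 3418. The last 3 comparisons gave 3189 and 7218, 2406 and 2065, and 1602 and 1459. For the share of abundant transcripts with separated groups, in the same order, the real and highest other splits were 9.97% and 27.6%, 8.2% and 18.8%, 23% and 19.6%, 16.1% and 24.8%, 22.6% and 15.1%, and 25.1% and 20.5%. For the set higher at 18 months the real camera p was 0.116 and the lowest other 0.29, with 1 split as low; for the set lower at 18 months they were 0.576 and 0.0105, with 9 splits as low. The split with 1265 calls puts the 3 low-complexity libraries of those ages on 1 side, and that with 61 sets them against the other libraries likewise, which points to a structure of the samples.

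Few distinct molecules read many times is a candidate explanation for the 4 libraries that missed transcripts. Among detected transcripts with whole counts, at most 6.61% had 1 to 5 reads in these libraries, against at least 32.6% in every other. Fewer reads are argued against, since 5 libraries with fewer reads detected more transcripts. So is removal of all low values, since 611 values of 1 to 5 reads remained, and so is age, since 5 libraries of the same ages detected more. Differences in RNA input or amplification stay open and were not tested.

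ENSMUST00000127786 was high in replicates 2 and 3 of the heterozygous group and was picked for that, so its own levels exclude no explanation. A difference between animals that the labels do not give, sex among them, may be the source. It would leave transcripts lost or present in this pair alone only if no wild type library shared it, which the labels do not tell. Absent here means 0 reads in both libraries of a pair and at least 3 CPM in the other libraries without low complexity. The libraries of low complexity could also hold 0 reads. By that count 18 were absent from this pair. The median over the other pairs was 2, with as many as 36 in another of the 55 pairs of libraries without low complexity. That other pair also held replicate 3 of the heterozygous group, where 14.2% of transcripts with a mean count of at least 20 had 0 reads. Present only in a pair means at least 10 CPM in both of its libraries and under 3 CPM in every other library. In that sense 3 were present only in this pair, ENSMUST00000127786 among them, against a median of 0 and at most 3 in another pair. Missed transcripts enter these counts too, so the counts cannot decide on a difference between animals, which stays open. The heterozygous allele was not tested. By the labels replicate 1 carries it as well, and there ENSMUST00000127786 was at 0.365 CPM. The allele alone therefore does not set this pair apart.

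In all, 15 transcripts had 0 reads in all 3 libraries of 1 group, a mean of at least 5 CPM elsewhere and reads in at least 11 of the 12 other libraries, ENSMUST00000152103 and ENSMUST00000179489 among them. The real groups did not stand out from other sets of 3 libraries in the number of such transcripts. Of the 5 groups, 0 exceeded 95% of the sets with as many low-complexity libraries. Random misses would give this too, but the other sets share these libraries, so the count cannot show that the misses were random. Without the minimum of 11 libraries the groups held 150, 154, 199, 127 and 62 at 1, 6, 12 and 18 months and in the heterozygous group, and again 0 groups exceeded. Assignment of reads to a related transcript may also contribute. ENSMUST00000179489 raised the idea: a row within 5 rows of it ran opposite in CPM, at r of -0.927. The lowest such r was -0.733 for ENSMUST00000229930, -0.688 for ENSMUST00000152103 and -0.132 for ENSMUST00000190894. Leaving out ENSMUST00000179489, 35.7% of the other 14 had such a row at r of -0.7 or below. Among random rows the share was 11% (Fisher's exact test, two-sided, p = 0.0144). Over 12 combinations of window and limit, 7 were under 0.05 and the exact p ran from 0.0113 to 0.328, so this was not settled for them. Without the minimum, the share was 26%, against 11% of random rows (Fisher's exact test, two-sided, p = 1.32e-15). For the same transcripts set beside rows at random positions it was 4.74% (Fisher's exact test, two-sided, p = 1.76e-21). All 12 combinations were under 0.05 against each control. The second control holds the same transcripts on both sides, which this test treats as independent. Nearby rows may not be independent either, so the size of these p values should not be relied on. A change in which transcript of a gene is used would give the same picture and was not tested.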
